A study of Homo sapiens with 16 samples.

How the data were processed

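The series measured messenger RNA in SW620 cells, a human colorectal cancer line, that carried either a scrambled control short hairpin RNA or a short hairpin RNA against the transcription factor ATF4. Both lines were sequenced untreated and after 24 h or 48 h in 5 µM 5-fluorouracil (5-FU), a pyrimidine analogue used as chemotherapy that blocks thymidylate synthase and is built into RNA and DNA. Groups were taken from the titles. The scramble line had 3 untreated libraries, 3 at 24 h and 2 at 48 h, and the shATF4 line had 3, 3 and 2. For the 4 libraries titled as 48 h the treatment tag of the labels reads 24 h. The title and the design text of the series both speak of a 48 h group, and these 4 libraries were therefore placed at 48 h. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

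Cells were grown in DMEM with fetal bovine serum, and RNA was extracted on RNeasy columns, per the labels' protocols. Messenger RNA was selected on oligo-dT beads, cDNA was made with random hexamers, the complementary strand was made with DNA polymerase I and RNase H, and fragments of 370 to 420 bp were selected, per the labels' protocols. Selection for poly(A) tails limits what can be said of RNAs without a tail, such as most histone transcripts and small non-coding RNAs. Reads were counted per gene by the authors with featureCounts 1.5.0-p3 on GRCh38 (hg38), per the submitters' processing notes, and the deposited values used here are these whole-number counts, not normalized. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. Genes that overlap another gene, or that have near-identical copies, can therefore share reads, and they are named as uncertain. The authors' deposited table also holds, per the file headers, a log2 fold change and an adjusted p-value for 7 of the comparisons, and a gene length in bp that came with the annotation. The test behind those p-values is not given in the sources used here. Gene coordinates are those of the authors' table, on GRCh38.

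Counts for 58735 genes in 16 libraries were read from the deposited table, with every library's column matched to its title. Total counts per library ran from 14571611 to 17824188. Genes were filtered with filterByExpr of edgeR 4.0.16 under R 4.3.3, which left 17309 genes holding 99.9% of all counts. Library sizes were scaled by TMM. A quasi-likelihood negative binomial model with the 6 groups as its terms was fitted to all 16 libraries, with 10 residual degrees of freedom, so that the groups of 2 libraries shared the estimate of spread of the others. The common biological coefficient of variation was 0.0847. Adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test over the 17309 genes, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the F statistic of the same test. Levels are given as CPM on the TMM-scaled library size, with the SD between libraries. They rest on counting reads without molecular identifiers, so intervals cover counting error only. Where a group's summed count was 0, the fold was set against 3 counts over the group and is given as a lower bound. Where it was 1 to 3, the ratio of counts is given with its 95% exact binomial interval.

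There were 11 comparisons: ATF4 knockdown against scramble at each of the 3 states, 5-FU against untreated at each time in each line, 48 h against 24 h in each line, and, for each time, the interaction contrast that tests whether the response to 5-FU differed between the lines. A set of 34 gene lists was tested in each comparison with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 374 tests. Of these tests 165 passed, and 59 of the 165 also passed with a correlation estimated from the data, which takes each list's own spread into account and is harder to pass. For each list the number of genes called over all genes tested is given beside the number called when p-values were adjusted over the list alone. One list named for replication-dependent histones includes H1F0, which encodes the linker histone H1.0 and is replication-independent, and HIST1H2AC, HIST1H2BD and HIST1H2BK, which are known to give polyadenylated transcripts as well.

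The grouping, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined, except for 3 alternatives named below. The rule named ATF4 in every library and comparison. It named in each comparison the 5 protein-coding genes with the largest rise and the 5 with the largest fall among called genes with a mean of at least 1 CPM and no overlap between the groups, or 3 and 3 in the interaction and 48 h against 24 h comparisons, where overlap was not considered for the interaction. It also named up to 4 members of each list with the smallest adjusted p, and TYMS, DPYD, DDIT3, CHAC1, ASNS, TNF, CDKN1A and EIF2AK3 in any comparison. Some genes that the rule names are not reported here.

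Alternatives to the settings above were median-of-ratios size factors, upper-quartile scaling, no filter on low counts, the replicate number as a block, the test of DESeq2 1.42.0, a fit to the compared groups alone, a 2-fold minimum, and leaving out each library in turn. For single genes and lists the libraries left out were those of the compared groups. Alternatives chosen after seeing the data were per-library offsets for GC content and gene length, with GC content known for 17299 of the 17309 genes, leaving out together both libraries that stood apart from their groups, and upper-quartile scaling for the gene lists. Upper-quartile scaling moved the median log2 change of all genes at 48 h of 5-FU from 0.03 to 0.17 in scramble cells and from 0.03 to 0.16 in shATF4 cells, so directions at 48 h are relative to that choice, and list medians that changed sign under a scaling are named with the result or in the closing part.

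The fit was tested on simulated counts drawn from the real means and library sizes with 200 changed genes. For knockdown in untreated cells, with 3 libraries a group, 74.6% of genes changed 1.5-fold, 80.6% of genes changed 2-fold and 87.9% of genes changed 4-fold were recovered among 16631 genes tested, and 3.57% of the calls were false. For knockdown at 48 h, with 2 libraries a group, the recovered shares were 41.8%, 67.2% and 86.4% among 16598 genes, with 7.14% of the calls false. For the interaction at 48 h they were 25.4%, 53.7% and 77.3% among 16605 genes, with 7.96% of the calls false. These rates hold for the simulated counts. In the real data the knockdown count at 48 h moved from 1636 to 2463 without shATF4 24 h replicate 3. That library is outside the comparison and enters through the shared estimate of spread. The rates in the real data may therefore differ and were not measured. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.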

Results

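The data are counts of RNA sequencing reads per gene in 16 libraries of SW620 cells. Scramble cells and cells with a hairpin against ATF4 (shATF4) had 3 untreated libraries each, 3 libraries each after 24 h in 5 µM 5-FU and 2 each after 48 h. Total counts ran from 14571611 to 17824188 per library. The aims stated for the series concern the role of ATF4, the transcription factor of the integrated stress response, in the resistance of colorectal cancer cells to chemotherapy, and its title links TNF-α to PERK and ATF4. A pair of libraries stood apart from their groups. In scramble untreated replicate 2 the mitochondrially encoded protein-coding genes took 1.42% of counts, against 0.753% and 0.766% in replicates 1 and 3. In shATF4 24 h replicate 3 the signal recognition particle RNA (RN7SL) took 0.0713% of counts and mitochondrial ribosomal RNA 1.45%, against 0.0224% and 0.0241% and against 1.23% and 1.14% in replicates 1 and 2. The scramble 24 h libraries had 0.00424% to 0.00614% of RN7SL, below all 3 shATF4 24 h libraries.

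ATF4, the knockdown target (chromosome 22, 39519695 to 39522685, plus strand, GRCh38), was lower in all 8 shATF4 libraries than in all 8 scramble libraries. Untreated scramble libraries had 387.7, 363.6 and 383.7 CPM, and untreated shATF4 libraries had 171.8, 168.6 and 178.7 CPM. At 24 h the scramble libraries had 270.1, 285.3 and 280.1 CPM and the shATF4 libraries 91.1, 108.6 and 130.4 CPM. At 48 h the values were 331.1 and 332.8 CPM against 114 and 118.1 CPM. These levels rested on 1460 to 5734 counts of ATF4 per library. The knockdown was 2.19-fold untreated (log2 change -1.13 ± 0.09 SE, 3 against 3 libraries, adjusted p = 6.42e-08), 2.53-fold at 24 h (-1.34 ± 0.09, adjusted p = 2.7e-09) and 2.86-fold at 48 h (-1.52 ± 0.11, 2 against 2, adjusted p = 1.62e-08). These are values of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. ATF4 mRNA did not rise with 5-FU. It fell by 0.44 ± 0.09 on the log2 scale at 24 h in scramble cells (adjusted p = 0.000259). In shATF4 cells the log2 change was -0.65 ± 0.09 at 24 h (adjusted p = 4.07e-06) and -0.58 ± 0.10 at 48 h (adjusted p = 3.84e-05). In scramble cells at 48 h it was -0.19 ± 0.10 (adjusted p = 0.0934). The difference between the lines in that response did not pass at 24 h (-0.21 ± 0.12, adjusted p = 0.374) or at 48 h (-0.39 ± 0.14, adjusted p = 0.144). From 24 h to 48 h ATF4 changed by 0.25 in scramble cells (adjusted p = 0.0394) and by 0.08 in shATF4 cells (adjusted p = 0.543). The former call was lost when any 1 of the 5 libraries was left out. Its adjusted p was 0.123, 0.066 and 0.0861 without 24 h replicates 1, 2 and 3 and 0.164 and 0.181 without 48 h replicates 1 and 2.

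**Figure D1:**
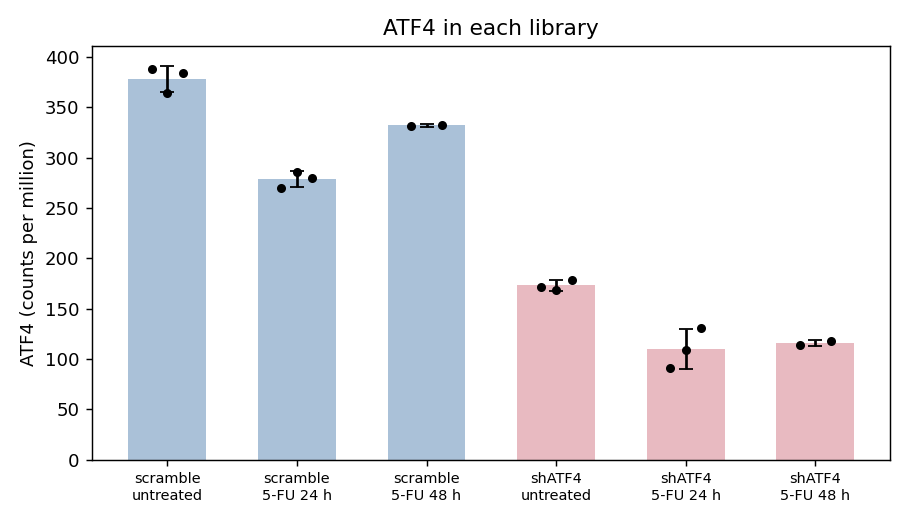
ATF4 level in CPM on TMM-scaled library size (vertical axis) in the 6 groups, with bars for group means, error bars for the SD and points for single libraries. The shATF4 libraries lie between 91.1 and 178.7 CPM and the scramble libraries between 270.1 and 387.7 CPM.

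Knockdown in untreated cells compares the shATF4 line with the scramble line before any drug. A single hairpin line was compared with a single control line. Loss of ATF4 therefore cannot be told apart from off-target effects or other differences between the lines, in any knockdown or interaction result. In shATF4 cells the serine synthesis enzyme PHGDH was 1.92-fold lower (log2 change -0.94 ± 0.09, 3 against 3 libraries, adjusted p = 1.02e-06). The stress-induced mTORC1 inhibitor DDIT4 was 2.4-fold lower (-1.26 ± 0.19, adjusted p = 0.000342). Fibronectin, FN1, was 2.97-fold higher, with 124.9 ± 6.6 CPM in scramble and 370.8 ± 5.2 CPM in shATF4 cells (SD, n = 3 each; log2 change 1.57 ± 0.08, adjusted p = 1.19e-10). The intermediate filament gene VIM fell (-0.74 ± 0.09, adjusted p = 2.02e-05). The Paneth cell defensin DEFA5 rose 4.24-fold (2.09 ± 0.15, adjusted p = 3.06e-08) and the coagulation factor gene F13A1 5.39-fold (2.43 ± 0.27, adjusted p = 9.61e-06). In total 506 of 17309 genes were called, 187 higher and 319 lower, of which 90 changed at least 2-fold, 54 of them higher and 36 lower. The count rested on each library in part, falling to 295 without scramble untreated replicate 1 and to 327, 277 and 312 without shATF4 untreated replicates 1, 2 and 3. It rose to 774 without shATF4 24 h replicate 3, which is outside this comparison and enters through the shared estimate of spread, and was 891 without both libraries that stood apart, a check chosen after seeing the data.

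Among the genes with the largest rises CLEC18B stood at 2.18 ± 0.31 (adjusted p = 0.000248), but it has near-identical copies that can share its reads. LAMC3, a laminin chain, stood at 2.04 (adjusted p = 0.00852), a call lost without scramble replicate 3 (0.0504) or shATF4 replicate 3 (0.0669). DUSP8, a phosphatase of stress kinases, stood at 2.01 (adjusted p = 0.00877), lost without scramble replicate 3 (0.0532) or shATF4 replicate 3 (0.0608). TMEM159 (-1.79 ± 0.32, adjusted p = 0.00233) and RASSF2, a tumour suppressor that binds RAS (-1.76 ± 0.36, adjusted p = 0.00665), were among the largest falls. RFX8 had -2.56 ± 0.64 (adjusted p = 0.0293), lost without scramble replicate 1 (0.103) or 3 (0.0858) and without shATF4 replicate 1 (0.0858), 2 (0.0939) or 3 (0.121). LYPD3 had -1.77 ± 0.42 (adjusted p = 0.0205), lost without scramble replicate 1 (0.0727) or 3 (0.0686) or shATF4 replicate 1 (0.113) or 3 (0.0804).

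Of the 17 integrated stress response regulators measured, DDIT4 was called and fell, or 7 fell and 1 rose when adjusted over the list alone, and the list as a whole was lower (median -0.22, camera adjusted p = 0.00093, and 0.0392 with an estimated correlation). The transcription factor DDIT3, also called CHOP, did not pass (0.42, adjusted p = 0.161), nor did the glutathione-degrading enzyme CHAC1 (-0.23, adjusted p = 0.614). Among 14 amino acid synthesis and one-carbon enzymes 3 fell, also 3 when adjusted over the list alone, with a median of -0.10 (camera adjusted p = 0.00453, and 0.046 with an estimated correlation). The median was -0.15 without scramble replicate 2 and -0.06 without scramble replicate 3. ASNS, asparagine synthetase, was near 0.9 CPM and did not pass (0.18, adjusted p = 0.893). Of 18 hypoxia and glycolysis genes 2 fell, among them the prolyl hydroxylase EGLN3 (-0.73 ± 0.14, adjusted p = 0.00424), or 1 rose and 3 fell when adjusted over the list alone (median -0.19, camera adjusted p = 0.0019, and 0.0308 with an estimated correlation). Of 11 mesenchymal and invasion genes 3 rose and 2 fell, or 4 and 4 adjusted over the list alone (median 0.07, camera adjusted p = 0.00503, and 0.0492 with an estimated correlation). That median was 0.03 and 0.12 without scramble replicates 2 and 3 and 0.14 without shATF4 replicate 2. FN1 and the matrix protease MMP7 (0.94 ± 0.17, adjusted p = 0.00238) were among the members that rose. Replication-dependent histone genes were higher, with 3 of 10 called and 4 adjusted over the list alone (median 0.61, camera adjusted p = 1.11e-06, and 0.00606 with an estimated correlation), among them HIST1H2AC (0.84 ± 0.12, adjusted p = 0.000128). The decoy death receptor TNFRSF10D (0.61 ± 0.09, adjusted p = 0.000279) and the drug efflux pump ABCB1 (0.66 ± 0.12, adjusted p = 0.00312) rose as well. The 13 mitochondrially encoded genes had a median of -0.42, with 1 called lower, or 8 adjusted over the list alone (camera adjusted p = 0.000142, and 0.332 with an estimated correlation). Without scramble untreated replicate 2, the library with the high mitochondrial share, that median was -0.04 (adjusted p = 0.599). Any list given with a single count had that same count adjusted over the list alone. The 5-FU target thymidylate synthase, TYMS (-0.18, adjusted p = 0.249), the 5-FU degrading enzyme DPYD (1.94 ± 0.56, adjusted p = 0.0672) and TNF (1.14 ± 0.92, adjusted p = 0.65) did not pass. Nor did CDKN1A (0.42, adjusted p = 0.574) or the PERK gene EIF2AK3 (-0.06, adjusted p = 0.905).

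The response of scramble cells to 24 h of 5-FU compares treated with untreated cells in the control line. No time is given for the untreated libraries, and the same ones served as baseline at 24 h and 48 h. Time in culture therefore cannot be told apart from the drug in the 5-FU comparisons of either line, nor between 24 h and 48 h. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose 14.9-fold from 1.36 ± 0.80 to 20 ± 1.4 CPM (SD, n = 3 each; log2 change 3.90 ± 0.20, adjusted p = 5.38e-12). NF-κB targets rose, the chemokine gene CCL20 by 4.84-fold (2.27 ± 0.14, adjusted p = 5.3e-11) and CXCL8, interleukin 8, by 2.67 ± 0.16 on the log2 scale (adjusted p = 5.41e-11), and TNF itself rose 8.62-fold from a low level (3.11 ± 0.71, adjusted p = 0.00119). The intestinal keratin KRT20 rose 7.55-fold (2.92 ± 0.18, adjusted p = 1.07e-10), while the mitotic kinase PLK1 (-1.40 ± 0.07, adjusted p = 3.75e-12) and the ribosomal protein gene RPL3 (-1.62 ± 0.06, adjusted p = 2.03e-14) fell. At this time 7610 genes were called, 3769 higher and 3841 lower, and 1903 changed at least 2-fold, of which 1628 were higher. The share of called genes that were higher was 49.5%, with 51.5% under median-of-ratios size factors and 60.1% under upper-quartile scaling.

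The largest rises at 24 h included the keratin KRT16, 35.2-fold (5.14 ± 0.53, adjusted p = 1.22e-07), set against 4 counts untreated that were all in replicate 2. Without that library its untreated count was 0, so the rise held (adjusted p = 1.84e-07) but the size of the fold rests on 1 untreated library. The adaptor gene HSH2D and the cytokine gene CSF2 (GM-CSF) had 1 to 3 counts in untreated scramble cells, so their count ratios are given, 61.9 (95% interval 10.8 to 2478) and 60.1 (10.4 to 2408). DUSP13 had a ratio of 25.6 (8.49 to 127), and the skin protease KLK5, with no counts untreated, was at least 2.65-fold higher (adjusted p = 0.00719). The largest falls were in DHRS2, a short-chain reductase (13.5-fold, -3.75 ± 0.37, adjusted p = 6.9e-08), and ACTL8 (-2.89 ± 0.47, adjusted p = 4.01e-05). The histone genes HIST1H2AC (-2.34 ± 0.15, adjusted p = 1.14e-10) and HIST2H2BE (-2.26 ± 0.28, adjusted p = 1.56e-06) were close behind. NUTM2B stood at -2.33 ± 0.51 (adjusted p = 0.000916) but has near-identical copies.

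Of 20 TNF and NF-κB target genes 19 rose at 24 h, or 19 rose and 1 fell when adjusted over the list alone (median 1.48, camera adjusted p = 1.77e-18). The noncanonical NF-κB subunit NFKB2 (1.59 ± 0.10) and the chemokine CXCL1 (1.75 ± 0.12) were among them. Of 18 interferon-stimulated genes 14 rose, also 14 adjusted over the list alone (median 0.84, camera adjusted p = 2.62e-06), with the antiviral enzyme gene OAS1 at 1.55 ± 0.13. Of 44 ribosomal protein genes 43 fell, or 44 adjusted over the list alone (median -0.73, camera adjusted p = 3.39e-26, but 0.129 with an estimated correlation). Of ribosome biogenesis genes 22 of 25 fell, NPM1 among them (-1.04 ± 0.08; list median -0.53, camera adjusted p = 1.76e-11). Of 28 G2 and mitosis genes 21 fell (median -0.57, camera adjusted p = 3.15e-15), such as the mitotic regulator CDC20 (-1.22 ± 0.07) and the spindle protein HMMR (-1.51 ± 0.09). Cholesterol synthesis genes fell, 14 of 20 (median -0.41, camera adjusted p = 8.96e-07), with HMGCS1 at -0.90 ± 0.09 and the sterol sensor INSIG1 at -1.43 ± 0.11. Of 10 heat shock genes 8 fell (median -0.47, camera adjusted p = 0.000144), HSPA8 by 2.37-fold. Of 23 endoplasmic reticulum chaperone and unfolded protein response genes 12 fell and 1 rose (median -0.27, camera adjusted p = 0.00153), and the chaperone BiP, HSPA5, fell (-0.98 ± 0.06, adjusted p = 2.97e-11). Of 11 mesenchymal and invasion genes 7 rose (median 0.64, camera adjusted p = 2.63e-09), and the median was 0.37 without untreated replicate 2, the library with the high mitochondrial share.

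Of 23 p53 target genes 11 rose and 2 fell at 24 h in scramble cells, or 12 and 2 adjusted over the list alone (median 0.22, camera adjusted p = 0.00865, but 0.0585 with an estimated correlation). CDKN1A and the death receptor FAS (1.70 ± 0.30) were among those that rose. Of 17 integrated stress response regulators 9 rose and 1 fell (median 0.43, camera adjusted p = 0.00403, but 0.0586 with an estimated correlation). The cytokine GDF15 rose 3.48-fold (1.80 ± 0.08) and CHAC1 by 0.63 ± 0.16 (adjusted p = 0.00263). DDIT3 stood at 0.38 (adjusted p = 0.0408), a call lost without untreated replicate 1 (0.0683) or 3 (0.154), without 24 h replicate 2 (0.141) or 3 (0.0643), and with DESeq2 (0.0603). ATF4-target aminoacyl-tRNA synthetases fell, 10 of 13, or 11 adjusted over the list alone (median -0.41, camera adjusted p = 0.000324, but 0.134 with an estimated correlation). The list of other cytosolic aminoacyl-tRNA synthetases had a median of -0.286, so the fall was not particular to ATF4 targets. At 48 h in scramble cells its median was -0.725, against -0.565 for the ATF4 targets. Amino acid synthesis and one-carbon enzymes fell in 6 of 14 cases and rose in 1, or 7 and 1 adjusted over the list alone (median -0.23, camera adjusted p = 0.0116, but 0.0602 with an estimated correlation), with the mitochondrial folate enzyme MTHFD1L at -0.95 ± 0.07. TYMS (0.07, adjusted p = 0.476), DPYD (0.33, adjusted p = 0.729), ASNS (-0.72, adjusted p = 0.146) and EIF2AK3 (0.12, adjusted p = 0.476) did not pass.

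At 48 h the response of scramble cells covered 10501 genes, 5301 higher and 5200 lower, with 4189 changed at least 2-fold, of which 3142 were higher. CDKN1A stood 37.4-fold above untreated cells (5.22 ± 0.20, 2 against 3 libraries, adjusted p = 1.24e-14) and CCL20 8.62-fold (3.11 ± 0.14, adjusted p = 2.17e-13). The adhesion molecule gene ICAM1 was 12.8-fold higher (3.68 ± 0.18, adjusted p = 7.86e-13) and TNF 9.93-fold (3.31 ± 0.74, adjusted p = 0.000567). DDIT3 rose 3.1-fold (1.63 ± 0.15, adjusted p = 6.43e-09), CHAC1 by 1.49 ± 0.16 on the log2 scale (adjusted p = 1.09e-07) and the eIF2α phosphatase subunit PPP1R15A by 1.91 ± 0.08 (adjusted p = 6.25e-14). TYMS was slightly lower (-0.33 ± 0.08, adjusted p = 0.00179). Under upper-quartile scaling 61.4% of called genes were higher, against 50.5%.

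By size of change at 48 h, KLK5 was at least 156-fold higher and SPTSSB, a subunit of the enzyme that starts sphingolipid synthesis, at least 49.8-fold, both with no counts untreated. HSH2D had a count ratio of 204 (95% interval 36.1 to 8105), CSF2 of 156 (27.5 to 6207) and the carboxypeptidase gene CPA4 of 154 (52.2 to 749). The falls were led by the acyltransferase gene GPAT2 (-4.23 ± 0.27, adjusted p = 2.88e-11) and MGAM2 (-3.92 ± 0.23, adjusted p = 8.07e-12), with CHODL at -3.51 ± 0.32, HSD17B8 at -3.28 ± 0.29 and FDXACB1 at -3.21 ± 0.53.

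Of the 20 TNF and NF-κB targets 19 were higher and 1 lower at 48 h (median 1.78, camera adjusted p = 8.1e-12), and 16 of 18 interferon-stimulated genes rose (median 1.72, camera adjusted p = 2.41e-08), IFI6 by 2.48 ± 0.14. All 44 ribosomal protein genes fell (median -1.31, camera adjusted p = 2.95e-28, but 0.117 with an estimated correlation), RPL3 to -2.20 ± 0.07. Of 17 stress response regulators 12 rose and 2 fell (median 1.31, camera adjusted p = 2e-05). Of 14 amino acid synthesis and one-carbon enzymes 8 fell and 2 rose (median -0.57, camera adjusted p = 3.36e-05), such as MTHFD1L (-2.18 ± 0.08) and SHMT2 (-1.61). Of 20 cholesterol synthesis genes 18 fell (median -0.71, camera adjusted p = 1.91e-07). Of 12 immediate early and AP-1 genes 10 rose (median 1.15, camera adjusted p = 4.24e-07), FOS by 3.14. Wnt target and intestinal stem cell genes fell, 11 of 16 against 2 that rose (median -0.63, camera adjusted p = 7.36e-06, but 0.117 with an estimated correlation), among them NOTUM (-2.72) and SMOC2 (-2.71). Of 15 colon epithelial genes 8 rose and 5 fell and the list did not pass (camera adjusted p = 0.138), with KRT20 at 2.89 ± 0.20 and the mucin MUC13 at 2.47 but the brush border gene VIL1 at -1.48. Of 17 fluoropyrimidine and nucleotide metabolism genes 5 rose and 6 fell, or 6 and 6 adjusted over the list alone (camera adjusted p = 0.751). DPYD (1.23, adjusted p = 0.106), ASNS (0.04, adjusted p = 0.947) and EIF2AK3 (0.11, adjusted p = 0.514) did not pass.

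**Figure D2:**
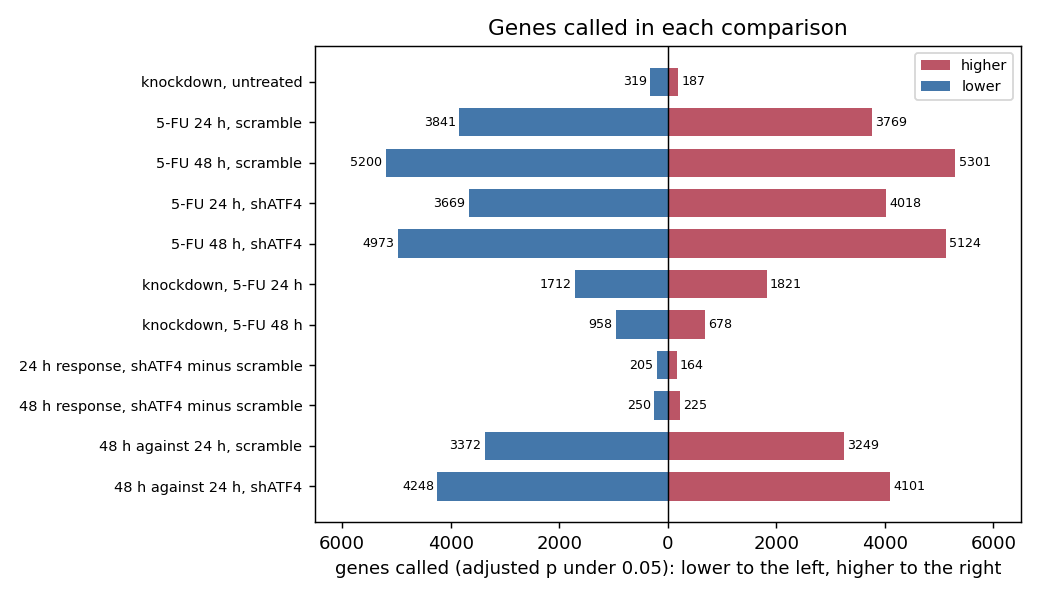
Genes called by edgeR at an adjusted p under 0.05 in the 11 comparisons (vertical axis), with bars to the right for the number of genes higher and to the left for the number lower. The bars for 48 h of 5-FU in scramble cells reach 5301 and 5200 genes, and those for knockdown in untreated cells 187 and 319.

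In shATF4 cells 24 h of 5-FU changed 7687 genes, 4018 higher and 3669 lower, with 1856 changed at least 2-fold, of which 1443 were higher. CDKN1A rose 9.72-fold (3.28 ± 0.19, 3 against 3 libraries, adjusted p = 5.04e-11), CCL20 by 2.60 ± 0.13 (adjusted p = 6.18e-12), CXCL8 by 3.06, GDF15 by 2.31 and KRT20 by 2.50. TNF rose by 2.25 ± 0.59 (adjusted p = 0.00399). The mucin gene MUC2, with 1 to 3 counts untreated, had a count ratio of 81.3 (95% interval 14.2 to 3247), and the checkpoint receptor gene PDCD1 one of 22.1 (5.81 to 188). KRT16 rose by 4.74 ± 0.49, the endothelial receptor gene ACVRL1 by 4.46 ± 0.35 and PTPN7 by 4.40 ± 0.37. DHRS2 (-3.81 ± 0.31), HIST3H2A (-2.36 ± 0.15), HIST2H2BE (-2.34), PSD2 (-2.27) and HIST1H2AC (-2.08 ± 0.13, adjusted p = 8.61e-11) were the largest falls. Of the 20 TNF and NF-κB targets 19 rose and 1 fell (median 1.45, camera adjusted p = 5.48e-22), and of 18 interferon-stimulated genes 13 rose (median 0.74, camera adjusted p = 0.000171). Of 44 ribosomal protein genes 29 fell, or 30 adjusted over the list alone (median -0.33, camera adjusted p = 2.41e-08, but 0.38 with an estimated correlation). The ribosomal median was -0.54 without 24 h replicate 3, the library with the high RN7SL share. Of 28 G2 and mitosis genes 18 fell, or 20 adjusted over the list alone (median -0.45, camera adjusted p = 1.12e-11). ATF4-target aminoacyl-tRNA synthetases fell in 12 of 13 cases (median -0.49, camera adjusted p = 1.1e-07, and 0.0492 with an estimated correlation), with GARS at -0.91 ± 0.07. The other cytosolic aminoacyl-tRNA synthetases were lower too (median -0.277). That call was lost without untreated replicate 1 (camera adjusted p = 0.0522) or 3 (0.0544), without 24 h replicate 1 (0.0716) and under upper-quartile scaling (0.0633). Mitochondrially encoded genes rose, 12 of 13 (median 0.80, camera adjusted p = 0.000909, but 0.38 with an estimated correlation), in the group that includes replicate 3 with its high mitochondrial ribosomal RNA. Of 17 stress response regulators 5 rose and 2 fell (median 0.29, camera adjusted p = 0.0433, 0.141 with an estimated correlation), a call lost without untreated replicate 2 (0.0689) or 24 h replicate 1 (0.0507). Its median was 0.12 without 24 h replicate 3. DDIT3 (0.27, adjusted p = 0.118), CHAC1 (-0.02, adjusted p = 0.942), DPYD (-0.71, adjusted p = 0.231) and EIF2AK3 (-0.07, adjusted p = 0.679) did not pass. ASNS stood at -1.34 ± 0.41 (adjusted p = 0.0108), lost without untreated replicate 2 (0.0687) or 24 h replicate 3 (0.0648), and TYMS at 0.20 (adjusted p = 0.0359), lost without untreated replicate 1 (0.0969), 2 (0.0901) or 3 (0.0518) or 24 h replicate 2 (0.171).

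After 48 h in shATF4 cells 10097 genes were called, 5124 higher and 4973 lower, with 3743 changed at least 2-fold, of which 2881 were higher. CDKN1A rose 26.4-fold (4.72 ± 0.19, 2 against 3 libraries, adjusted p = 3.99e-14), CCL20 13.1-fold (3.71 ± 0.14, adjusted p = 2.14e-14) and TNF by 2.96 ± 0.59 (adjusted p = 0.000199). FN1 fell by 1.99 ± 0.09 on the log2 scale (adjusted p = 4.66e-13) and PHGDH rose by 1.20 ± 0.09 (adjusted p = 9.35e-10). Both started from untreated levels that differed between the lines. SPTSSB had a count ratio of 94.4 (95% interval 25.7 to 786), MUC2 of 86.1 (15 to 3446) and PDCD1 of 57.8 (15.6 to 484), and WNT9A rose by 5.66 ± 0.51 and the growth factor receptor EGFR by 5.62 ± 0.47. GPAT2 (-4.10), LIX1 (-3.87), MGAM2 (-3.39), MYRIP (-3.26) and the matrix glycoprotein gene TNC (-3.20 ± 0.08, adjusted p = 1.49e-16) fell most. DDIT3 stood at 0.41 (adjusted p = 0.025), lost without untreated replicate 2 (0.0502) or 3 (0.0803) or 48 h replicate 2 (0.198). CHAC1 rose by 1.36 ± 0.17 (adjusted p = 7.44e-07) and PPP1R15A by 1.27. Of the TNF and NF-κB targets 19 of 20 rose and 1 fell (median 1.93, camera adjusted p = 1.77e-18), and of the interferon-stimulated genes 16 of 18 rose (median 1.70, camera adjusted p = 2.63e-09). Stress response regulators rose in 12 of 17 cases and fell in 2 (median 1.13, camera adjusted p = 0.000145). All 44 ribosomal protein genes fell (median -1.15, camera adjusted p = 2.16e-24, but 0.143 with an estimated correlation). TYMS was lower (-0.34, adjusted p = 0.0018). DPYD (0.39, adjusted p = 0.481), ASNS (-0.02, adjusted p = 0.963) and EIF2AK3 (0.06, adjusted p = 0.75) did not pass. Under upper-quartile scaling 61.2% of called genes were higher, against 50.8%.

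**Figure D3:**
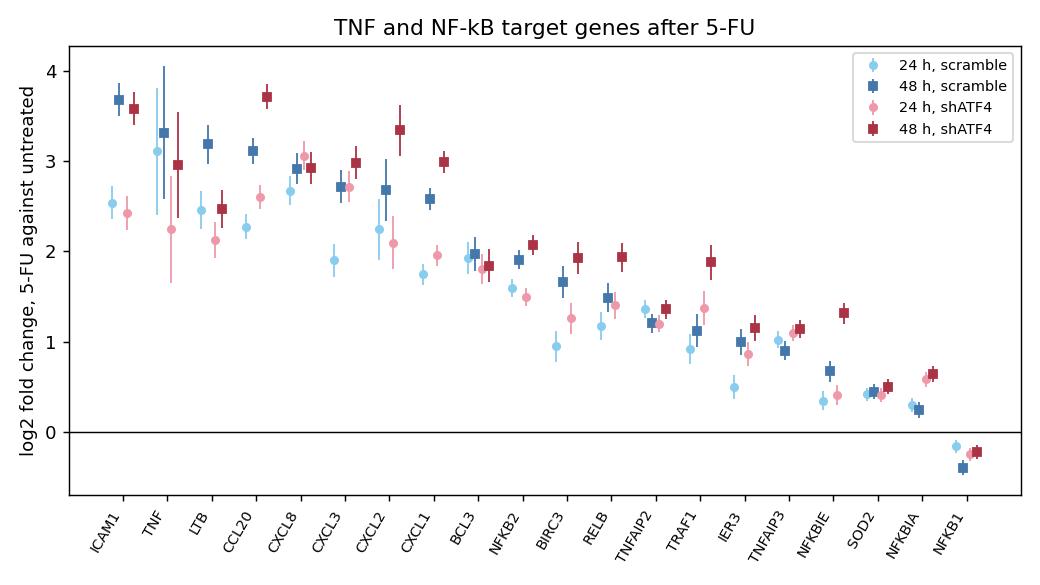
Log2 fold change (vertical axis; points are estimates and bars their SE) of 20 TNF and NF-κB target genes (horizontal axis, ordered by the change at 48 h in scramble cells) for 5-FU against untreated cells at 24 h and 48 h in both lines. CCL20 stands at 2.27 and 3.11 in scramble cells and at 2.60 and 3.71 in shATF4 cells.

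Between 24 h and 48 h of 5-FU 6621 genes changed in scramble cells, 3249 higher and 3372 lower, and 8349 in shATF4 cells, 4101 higher and 4248 lower. The scramble count was 4363 without 48 h replicate 2, and under upper-quartile scaling 60.2% of its genes were higher, against 49.1%. In shATF4 cells 58.6% were higher under that scaling, also against 49.1%, so the direction of both balances turned. Histone genes turned around. Of 10 replication-dependent histone genes 8 fell at 24 h in scramble cells (median -1.89, camera adjusted p = 2.97e-11) and 7 in shATF4 cells (median -1.71, camera adjusted p = 1.51e-12). From 24 h to 48 h 9 of 10 rose in each line, with medians of 2.97 (camera adjusted p = 1.81e-27) and 2.78 (camera adjusted p = 7.73e-21). HIST1H2AC rose by 3.66 ± 0.15 in scramble cells (3 against 2 libraries, adjusted p = 5.69e-13) and by 2.66 ± 0.13 in shATF4 cells (adjusted p = 7.16e-12), HIST1H2BD by 3.65 and 3.16, and H1F0, the linker histone that is independent of replication, by 1.15 and 1.34. Against untreated cells the 48 h medians were 1.05 in scramble cells with 7 of 10 genes higher and 1 lower (camera adjusted p = 0.0386, 0.122 with an estimated correlation). They were 0.93 in shATF4 cells with 7 higher and 1 lower (camera adjusted p = 0.0434, 0.131 with an estimated correlation). The former call was lost without scramble untreated replicate 3 (0.0547), and the latter without shATF4 untreated replicate 1 (0.0505) or 3 (0.0544) or 48 h replicate 2 (0.0726). Without both libraries that stood apart their adjusted p-values were 0.0571 and 0.0565, and with the replicate number as a block 0.0577 and 0.073. KLK5 rose by 5.82 ± 0.36 in scramble cells and at least 20-fold in shATF4 cells, SPTSSB by 5.27 and 4.83, WNT9A by 4.79 in scramble cells and IQGAP2 by 4.17 in shATF4 cells. The largest falls were in GPAT2 (-3.11), the transcription factor ST18 (-2.96) and MGAM2 (-2.75) in scramble cells, and in TNC (-3.52 ± 0.09, adjusted p = 6.12e-17), GPAT2 (-3.28) and ST18 (-3.11) in shATF4 cells. DDIT3 rose by 1.25 ± 0.14 in scramble cells (adjusted p = 8.09e-07) and stood at 0.14 in shATF4 cells (adjusted p = 0.474). Of 28 G2 and mitosis genes 13 rose and 2 fell in scramble cells (median 0.20, camera adjusted p = 0.0157, but 0.384 with an estimated correlation). In shATF4 cells 18 rose and 2 fell, or 19 and 2 adjusted over the list alone (median 0.31, camera adjusted p = 0.00193, but 0.285 with an estimated correlation).

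**Figure D4:**
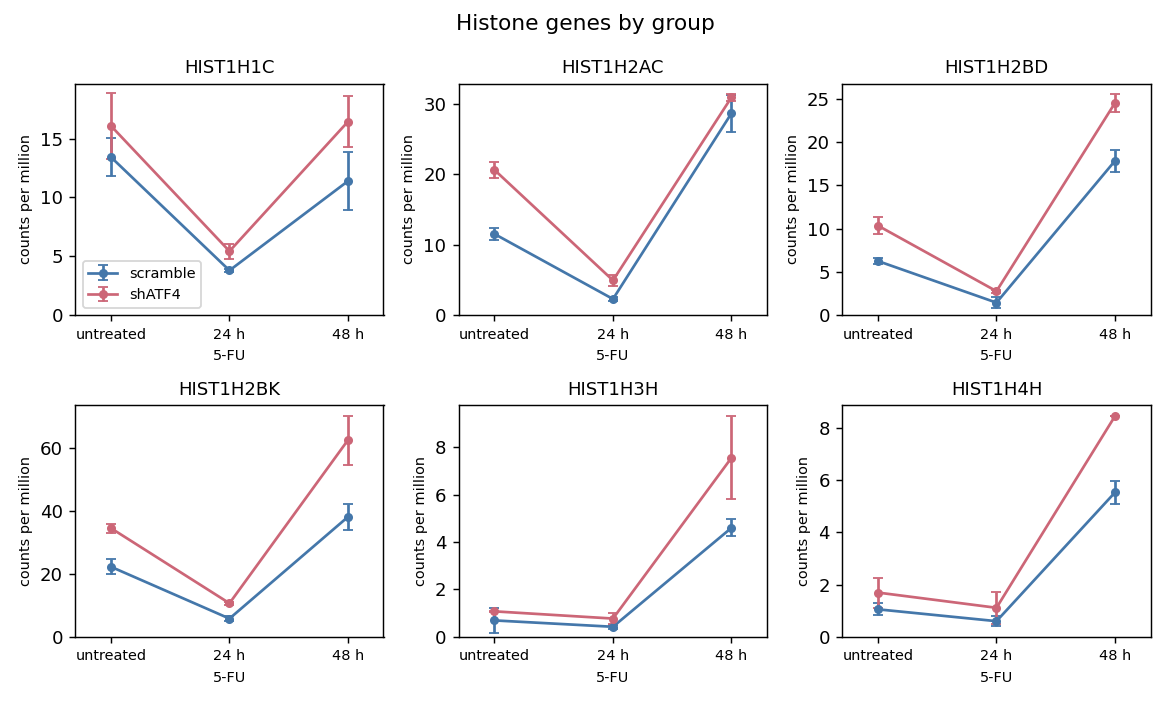
Mean level in CPM with the SD between libraries (vertical axis) of 6 histone genes, untreated and at 24 h and 48 h of 5-FU (horizontal axis), in scramble and shATF4 cells. HIST1H2AC stood at 11.5, 2.26 and 28.7 CPM in scramble cells and at 20.6, 4.91 and 31 CPM in shATF4 cells.

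Knockdown under 24 h of 5-FU compares the lines while cells respond to the drug. PHGDH was 2.27-fold lower in shATF4 cells (-1.19 ± 0.09, 3 against 3 libraries, adjusted p = 2.01e-08). Also lower were DDIT4 (-1.30 ± 0.18, adjusted p = 4.33e-05), CHAC1 (-0.88 ± 0.16, adjusted p = 0.000673) and the stress-induced peptide gene ADM2 (-1.34 ± 0.26, adjusted p = 0.00103). So were the tRNA synthetases GARS (-0.59 ± 0.07, adjusted p = 5.35e-06) and CARS (-0.55 ± 0.06, adjusted p = 9.45e-06). DEFA5 was 5.7-fold higher (2.51 ± 0.15, adjusted p = 9.8e-10), as were F13A1 (2.05 ± 0.21, adjusted p = 1.32e-06) and FN1 (1.28 ± 0.08, adjusted p = 1.46e-09). TNFRSF10D (1.06 ± 0.08, adjusted p = 5.27e-08) was higher too, with the chemokine genes CXCL3 (0.84 ± 0.14, adjusted p = 0.000436) and CCL20 (0.64 ± 0.12, adjusted p = 0.000662). In all 3533 genes were called, 1821 higher and 1712 lower, and 419 changed at least 2-fold, 203 higher and 216 lower. The balance turned with the scaling, from 51.5% higher to 46.3% with median-of-ratios size factors and 46.4% with upper-quartile factors. The count was 2067 without scramble 24 h replicate 1 and 2127 without scramble 24 h replicate 3.

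FBXW12 (1.83 ± 0.43, adjusted p = 0.00525) and the olfactory receptor gene OR51B5 (1.83 ± 0.24, adjusted p = 2.91e-05) were also among the largest rises at 24 h. NUTM2B, which has near-identical copies, had 1.94 (adjusted p = 0.0136). That call was lost without scramble 24 h replicate 1 (0.0641) or 2 (0.0573) or shATF4 24 h replicate 2 (0.0804). The largest falls were in the collagen gene COL6A3 (-2.90 ± 0.50, adjusted p = 0.000441), MYO1F (-2.68 ± 0.43, adjusted p = 0.000214) and RFX8 (-2.56 ± 0.46, adjusted p = 0.000611). SMIM11A, which has a near-identical copy, had -2.61 ± 0.53 (adjusted p = 0.00182), and KLK5 was at least 2.85-fold lower (adjusted p = 0.0151).

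Of 17 stress response regulators 9 were lower and 1 higher at 24 h (median -0.42, camera adjusted p = 0.000336, and 0.0308 with an estimated correlation), and DDIT3 did not pass (0.31, adjusted p = 0.112). Of 13 ATF4-target tRNA synthetases 5 were lower, or 6 adjusted over the list alone (median -0.16, camera adjusted p = 0.00127, but 0.164 with an estimated correlation). Ribosomal protein genes were higher, 37 of 44, or 41 adjusted over the list alone (median 0.37, camera adjusted p = 2.16e-15, but 0.242 with an estimated correlation), and the median was 0.21 without shATF4 24 h replicate 3. Of 25 ribosome biogenesis genes 10 were higher and 2 lower, or 11 against 3 adjusted over the list alone (median 0.16, camera adjusted p = 0.00228, but 0.164 with an estimated correlation), NCL at 0.40 among them. Of 20 cholesterol synthesis genes 6 were higher, or 7 adjusted over the list alone (median 0.16, camera adjusted p = 0.00397, and 0.0392 with an estimated correlation), and the median was 0.11 without shATF4 24 h replicate 3. Of 14 homologous recombination and Fanconi genes 6 were lower and 2 higher, or 7 and 3 adjusted over the list alone (median -0.16, camera adjusted p = 0.0168, but 0.339 with an estimated correlation), with FANCI at -0.68. Mitochondrially encoded genes were higher in 5 of 13 cases, or 9 adjusted over the list alone (median 0.45, camera adjusted p = 0.00114, but 0.39 with an estimated correlation). Mitochondrial ribosomal RNA took 1.14% to 1.45% of counts in the shATF4 libraries, against 0.881% to 0.955% in the scramble libraries. For RN7SL the shares were 0.0224% to 0.0713% against 0.00424% to 0.00614%. TYMS (-0.06, adjusted p = 0.646), DPYD (0.90, adjusted p = 0.267), ASNS (-0.44, adjusted p = 0.516), TNF (0.28, adjusted p = 0.713), CDKN1A (-0.20, adjusted p = 0.33) and EIF2AK3 (-0.25, adjusted p = 0.169) did not pass.

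Under 48 h of 5-FU DDIT3 (-0.81 ± 0.15, 2 against 2 libraries, adjusted p = 0.00182) and PPP1R15A (-0.75 ± 0.09, adjusted p = 9.73e-06) were lower in shATF4 cells. So were the glycoprotein hormone gene STC2 (-0.71 ± 0.11, adjusted p = 0.000201) and the glutamine transporter SLC38A2 (-0.57 ± 0.10, adjusted p = 0.000681). KRT20 was 6.43-fold lower (-2.68 ± 0.21, adjusted p = 7.12e-08) and the epithelial cadherin CDH1 stood at -0.64 ± 0.08 (adjusted p = 1.63e-05). ABCB1 was 2.35-fold higher (1.23 ± 0.13, adjusted p = 1.93e-06), and CCL20 (0.91 ± 0.14, adjusted p = 0.000158), CXCL2 (1.32 ± 0.26, adjusted p = 0.00257) and the intestinal transcription factor CDX2 (0.98 ± 0.15, adjusted p = 0.00015) were higher as well. The called genes numbered 1636, 678 higher and 958 lower, with 260 changed at least 2-fold, 73 higher and 187 lower. Leaving out 1 of the 2 libraries of a group moved the count to 602 or 600 without scramble 48 h replicate 1 or 2, and to 789 or 743 without shATF4 48 h replicate 1 or 2. It was 2463 without shATF4 24 h replicate 3 alone and 3021 without both libraries that stood apart, which are in other groups and enter through the shared estimate of spread.

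By size at 48 h, CHODL (2.41 ± 0.37, adjusted p = 0.000218), the butyrylcholinesterase gene BCHE (2.26 ± 0.32, adjusted p = 0.000102), OR2I1P (1.75 ± 0.15, adjusted p = 1.98e-07) and DEFA5 (1.70 ± 0.20, adjusted p = 1.44e-05) were among the highest. The lowest were the skin proteases KLK5 (-3.06 ± 0.32, adjusted p = 1.04e-05) and KLK7 (-2.62 ± 0.37, adjusted p = 8.82e-05), the phospholipase PLA2G2A (-2.80 ± 0.43, adjusted p = 0.000217), the calcium channel gene CACNA1E (-2.69 ± 0.40, adjusted p = 0.000157) and KRT20. Of 17 stress response regulators 5 were lower, or 8 adjusted over the list alone (median -0.32, camera adjusted p = 3.82e-05, and 0.0172 with an estimated correlation). Of 20 TNF and NF-κB targets 5 were higher, or 7 adjusted over the list alone (median 0.27, camera adjusted p = 0.000636, and 0.0427 with an estimated correlation). Of 11 mesenchymal and invasion genes 4 were lower, with 1 higher adjusted over the list alone (median -0.11, camera adjusted p = 0.00228, and 0.0386 with an estimated correlation), and the median was -0.17 without shATF4 48 h replicate 1. Of 15 colon epithelial genes 4 were lower and 2 higher, or 7 and 2 adjusted over the list alone (median -0.23, camera adjusted p = 0.0043, but 0.0695 with an estimated correlation). Of 12 immediate early and AP-1 genes 3 were lower, or 4 adjusted over the list alone (median -0.33, camera adjusted p = 0.00131, but 0.146 with an estimated correlation), among them KLF6 (-0.71 ± 0.10). The cystine transporter SLC7A11 stood at -0.90 (adjusted p = 0.0037, lost without scramble 48 h replicate 1, 0.0558, or shATF4 48 h replicate 2, 0.0728). The pseudokinase TRIB3 stood at -0.49 (adjusted p = 0.00371, lost without scramble 48 h replicate 2, 0.0542, or shATF4 48 h replicate 1, 0.0691). TYMS (-0.19, adjusted p = 0.227), DPYD (1.10, adjusted p = 0.221), CHAC1 (-0.36, adjusted p = 0.201) and ASNS (0.13, adjusted p = 0.902) did not pass. Neither did TNF (0.79, adjusted p = 0.389), CDKN1A (-0.08, adjusted p = 0.806) or EIF2AK3 (-0.11, adjusted p = 0.726).

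Whether the response to 5-FU differed between the lines was tested by the interaction. At 48 h the DDIT3 response was weaker in shATF4 cells by 1.22 ± 0.21 on the log2 scale (interaction -1.22, adjusted p = 0.00298). DDIT3 went from 5.97 ± 0.61 to 18.5 ± 0.3 CPM in scramble cells (SD, n = 3 and 2) and from 7.98 ± 0.58 to 10.6 ± 0.9 CPM in shATF4 cells. The PPP1R15A response was also weaker (-0.65 ± 0.12, adjusted p = 0.0039). KRT20 differed by -2.54 ± 0.33 (adjusted p = 0.000264), with 11.1 and 10.95 CPM at 24 h and 48 h in scramble cells and 7.5 and 1.7 CPM in shATF4 cells. FN1 differed by -1.60 ± 0.13 (adjusted p = 4.82e-07) and PHGDH by 0.98 ± 0.13 (adjusted p = 0.000338), both ending near the scramble level at 48 h, at 93.6 against 95.6 CPM for FN1 and at 64.3 against 62.4 CPM for PHGDH. CDH1 (-0.69 ± 0.10, adjusted p = 0.000573), the adhesion gene CEACAM6 (-1.48 ± 0.25, adjusted p = 0.00216) and the survival gene BCL2L1 (-0.51 ± 0.09, adjusted p = 0.00384) responded less. TYMS (-0.01, adjusted p = 0.994), CDKN1A (-0.50, adjusted p = 0.511), CHAC1 (-0.13, adjusted p = 0.861), TNF (-0.36, adjusted p = 0.908) and CCL20 (0.60, adjusted p = 0.126) did not pass. In total 475 genes passed at 48 h, 225 with a more positive change in shATF4 cells and 250 with a more negative one. The share more positive was 47.4%, with 38.6% under upper-quartile scaling, 45.8% with median-of-ratios size factors and 41.9% in the fit to its own groups. It was 47.5% with offsets and 49.9% without a filter. The balance turned with the replicate block (50.5%), with DESeq2 (52.7%) and without both libraries that stood apart (54.3%). The count was 267 without scramble untreated replicate 1, 265 without shATF4 untreated replicate 2, 173 and 136 without scramble 48 h replicates 1 and 2, 260 and 178 without shATF4 48 h replicates 1 and 2, 991 without shATF4 24 h replicate 3, outside this comparison, and 1204 without both libraries that stood apart.

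At 24 h 369 genes passed the interaction, 164 more positive in shATF4 cells and 205 more negative, so 44.4% were more positive. That share was 30.7% under upper-quartile scaling, 41.1% with median-of-ratios size factors, 43.7% with offsets and 37% in the fit to its own groups. The balance turned without a filter (60.3%), with DESeq2 (51.9%), with the replicate block (50.9%) and without both libraries that stood apart (57.3%). RPL3 fell less in shATF4 cells (0.40 ± 0.08, adjusted p = 0.0127, lost without scramble 24 h replicate 3, 0.052, or shATF4 untreated replicate 2, 0.0534). The ribosomal protein list differed in the same direction (median 0.39, 7 of 44 genes called, or 37 adjusted over the list alone, camera adjusted p = 3.45e-18, but 0.206 with an estimated correlation). The list's median was 0.23 without shATF4 24 h replicate 3. GARS had -0.43 ± 0.09 (adjusted p = 0.0225, lost without scramble untreated replicate 1, 0.0541, scramble 24 h replicate 3, 0.0666, shATF4 untreated replicate 1, 0.0605, or 2, 0.0629, or shATF4 24 h replicate 2, 0.0628). The death receptor TNFRSF10B had 0.46 ± 0.09 (adjusted p = 0.0162, lost without scramble 24 h replicate 3, 0.0625, or shATF4 untreated replicate 2, 0.0561). The autophagy gene WIPI1 had -1.31 ± 0.26 (adjusted p = 0.0147, lost without shATF4 untreated replicate 2, 0.0556). CHAC1 (-0.65, adjusted p = 0.137), DDIT3 (-0.11, adjusted p = 0.833), CDKN1A (-0.61, adjusted p = 0.313) and TNF (-0.86, adjusted p = 0.699) did not pass. The count rested on single libraries. It was 124 without scramble untreated replicate 1, 111, 192 and 87 without scramble 24 h replicates 1, 2 and 3, and 87, 65 and 210 without shATF4 untreated replicates 1, 2 and 3. Without shATF4 24 h replicates 1, 2 and 3 it was 1188, 114 and 678, and without both libraries that stood apart 647. Without scramble 48 h replicates 1 and 2, outside this comparison, it was 245 and 243.

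**Figure D5:**
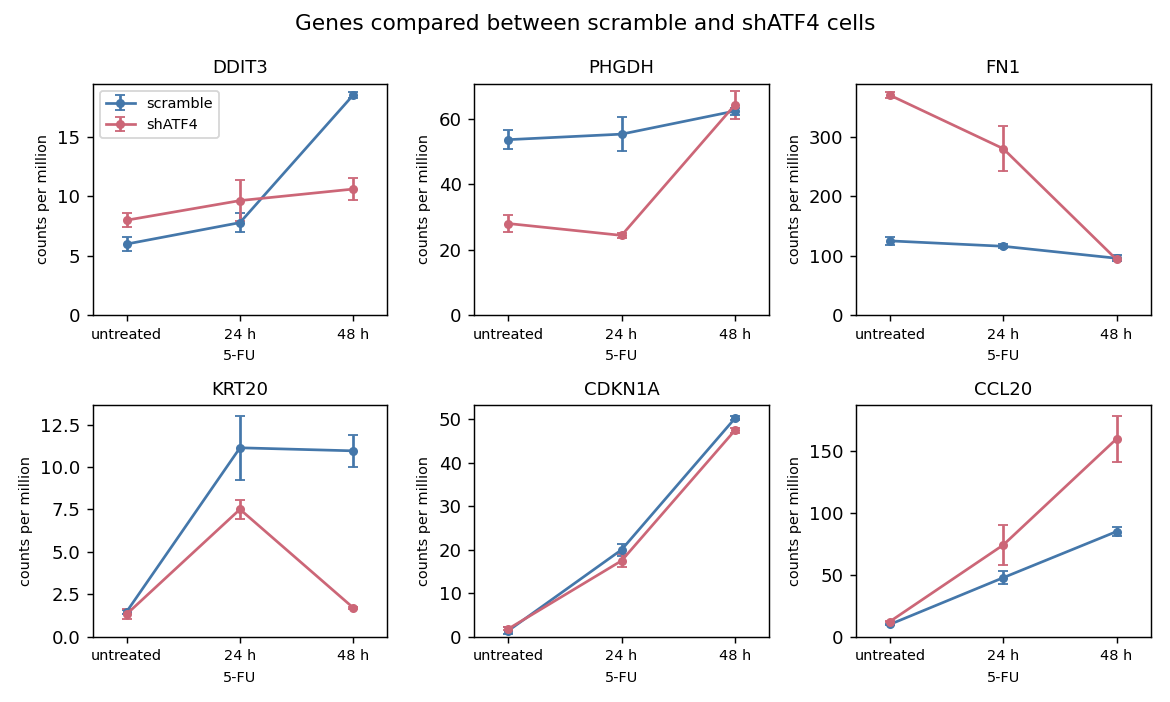
Mean level in CPM with the SD between libraries (vertical axis) of DDIT3, PHGDH, FN1, KRT20, CDKN1A and CCL20, untreated and at 24 h and 48 h of 5-FU (horizontal axis), in scramble and shATF4 cells. DDIT3 reached 18.5 CPM at 48 h in scramble cells and 10.6 CPM in shATF4 cells, and FN1 started at 124.9 and 370.8 CPM and ended at 95.6 and 93.6 CPM.

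The authors' deposited table called 437 genes for knockdown in untreated cells, 2081 at 24 h and 1702 at 48 h, of which 365, 2064 and 1277 were also called here, each in the same direction. For 5-FU it called 6657 and 8996 genes at 24 h and 48 h in scramble cells and 5727 and 8886 in shATF4 cells, of which 6447, 8788, 5690 and 8617 were shared, each in the same direction. Its ATF4 log2 changes with knockdown were -1.12, -1.35 and -1.51.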

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

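The tests that leave out a library, correct for GC content and length, set counts against the 48 h count of the same fit, follow the DNA replication list and take small RNAs as the whole cause were chosen after the results they bear on were seen, and the test on signs at 24 h was first read as in favour of chance and was judged to decide nothing only after its value was seen. The response to 5-FU differed between scramble and shATF4 cells by the interaction test for 369 genes at 24 h and for 475 at 48 h, and the lists and genes given at the end were picked out by that test. The count of knockdown genes at 24 h and the histone pattern were not picked out by it, and the histone list's interaction did not pass at 24 h (adjusted p = 0.736) or 48 h (0.297).

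At 24 h of 5-FU 3533 genes differed with the knockdown, against 506 untreated and 1636 at 48 h, but the order of the times turned in fits to the compared groups alone (2189 at 24 h and 2748 at 48 h), and the gap shrank without both libraries that stood apart (3822 and 3021). Offsets for GC content and length gave 4868 and 2965, and 24 h stayed above 48 h without each 24 h library (3688 to 5236 genes at 24 h). These fits kept more libraries at 24 h than at 48 h, which can raise the 24 h count with or without that bias. They therefore do not decide what part the bias plays. The library shATF4 24 h replicate 3 stays open, since 3204 genes were called at 24 h and 2463 at 48 h without it, but 2210 against 2270 and 2224 against 2254 without it and scramble 24 h replicate 1 or 3. Shares of RN7SL and mitochondrial ribosomal RNA were higher in every shATF4 24 h library than in every scramble 24 h library. What sets the whole group apart in these shares cannot be told apart from the knockdown at 24 h. More libraries at 24 h than at 48 h remain open too, since the 9 choices of 2 libraries a group gave a median of 2224 genes and a range of 1333 to 3204 that includes 1636, and 3 of the 9 lay below the 48 h count of their own fit. A hypothesis is that the 24 h response of shATF4 cells ran behind that of scramble cells. Of the 3533 genes 64% were opposite in sign to their 48 h change against untreated in shATF4 cells, a contrast with no library in common. The share was 61.9% to 65.1% when single libraries were left out and 50.2% if the changes were unrelated. Genes such as FN1, whose untreated difference between the lines was gone at 48 h, take opposite signs without a delay. The share therefore does not decide whether a delay accounts for part of the pattern.

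Histone genes fell at 24 h of 5-FU and were higher at 48 h than at 24 h, with list medians of 2.97 and 2.78 on the log2 scale in scramble and shATF4 cells. The DNA replication list did not rise with them, with medians of -0.22 and -0.16 from 24 h to 48 h. At 24 h against untreated its medians were 0.17 and 0.26. That list includes genes of entry into S phase, such as CCNE1 and CCNE2, whose transcripts need not follow DNA synthesis. It therefore does not decide whether the share of cells in S phase plays a part. Small RNAs without poly(A) tails had medians of 0.23 and -0.29 over 24 genes. Their upper quartiles of 0.65 and 0.33 lay below the histone medians. RN7SL genes, whose levels had been seen, were left out of that set. Small RNAs may be shorter than the fragments of 370 to 420 bp that were selected. They may therefore not follow a leak of histone transcripts through the poly(A) selection, and such a leak stays open. A change in histone transcript tails or amounts after 5-FU stays open as a biological explanation and was not tested.

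KRT20 was among the 475 genes that responded differently at 48 h. A weaker response of all genes in shATF4 cells could account for some of them, since the slope of shATF4 on scramble changes over 4318 genes was 0.911, with 0.844 to 0.961 when single libraries were left out. Signs at 24 h did not decide whether chance values of the untreated and 48 h libraries account for others. Of the 475 genes 42.5% had the same sign in the knockdown contrast at 24 h, with 41.7% to 44.4% when single libraries were left out, but genes such as FN1 (1.28 there, -1.60 in the interaction), whose untreated difference was gone at 48 h, take the opposite sign without chance. An effect of ATF4 on the late response stays open as well. DDIT3, PPP1R15A, FN1, PHGDH and KRT20 passed with each untreated library left out in turn. These fits reuse the data that gave the calls, so they are no separate evidence for such an effect. FN1 and PHGDH ended near the scramble level at 48 h, so their interaction is an untreated difference that was gone by then.

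For knockdown in untreated cells, 5-FU at 24 h in scramble cells, 5-FU at 24 h in shATF4 cells and knockdown at 24 h, the 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 506, 7610, 7687 and 3533 genes, and the highest other split gave 0 by edgeR in each, so 1 of the 10 splits was as large. For the interaction at 24 h, 7 of 100 splits gave at least the real 369 genes, where both numbers include the real split. The highest other split gave 2712. By the rule fixed beforehand, a share of 0.05 or more counted in favour of chance, and this result met it. A split with several times the real count points to a structure of the samples, here the difference between the lines, which such splits mix into the interaction. That reading was not part of the rule, and chance is not excluded for the interaction at 24 h.

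At 24 h the interaction also passed for lists with medians of 0.39 for ribosomal proteins, 0.21 for ribosome biogenesis genes, 0.78 for mitochondrially encoded genes, 0.15 for cholesterol synthesis, 0.17 for heat shock proteins (0.165) and -0.13 for ATF4-target tRNA synthetases, none of which passed with an estimated correlation (adjusted p from 0.0854 for cholesterol synthesis to 0.225 for the tRNA synthetases). The cholesterol list (adjusted p = 0.0324) was lost without scramble untreated replicate 3 (0.0638), scramble 24 h replicate 2 (0.0558) or 3 (0.056), shATF4 untreated replicate 2 (0.0623) or shATF4 24 h replicate 1 (0.0639) and under upper-quartile scaling (0.0547), and the heat shock list (0.0216) without shATF4 24 h replicate 3 (0.0699). The mitochondrial median was 0.45 without scramble untreated replicate 2, the library with 1.42% mitochondrial coding counts, the ribosomal median 0.23 without shATF4 24 h replicate 3, and the tRNA synthetase median -0.08 without scramble untreated replicate 2. Single genes with the largest differences at 24 h were SLC25A18 (2.22, adjusted p = 0.0431), MT-ND4L (1.42, 0.0301), MT-ND1 (1.20, 0.0253), MYO1F (-2.82, 0.045), JPH2 (-2.49, 0.0325) and EPAS1 (-2.44, 0.0363). Each of these 6 calls was lost when some library was left out. The highest adjusted p was 0.118 for SLC25A18, 0.123 for MYO1F and 0.132 for EPAS1 without shATF4 untreated replicate 2, 0.104 for JPH2 without shATF4 untreated replicate 1, 0.087 for MT-ND4L and 0.0828 for MT-ND1 without scramble 24 h replicate 1. Without scramble untreated replicate 2 the MT-ND4L call was lost (0.0808) and MT-ND1 stood at 0.71, and without shATF4 24 h replicate 3 MT-ND4L stood at 0.87.

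At 48 h the interaction passed for lists with medians of -0.35 for mesenchymal and invasion genes (adjusted p = 3.18e-06, and 0.00647 with an estimated correlation), -0.40 for colon epithelial genes, 0.14 for amino acid synthesis enzymes, 0.21 for TNF and NF-κB targets (0.209), 0.16 for G2 and mitosis genes (0.155), 0.16 for NRF2 targets, 0.20 for hypoxia and glycolysis genes, 0.21 for ribosomal proteins (0.207) and 0.29 for heat shock proteins. With an estimated correlation the mesenchymal list was the only 1 of these 9 to pass, and the others had adjusted p from 0.0576 for the colon list to 0.491 for ribosomal proteins. The mesenchymal median was -0.20 and -0.23 without scramble untreated replicates 2 and 3, the colon median -0.24 without scramble untreated replicate 3, and the NRF2 median 0.10 without scramble 48 h replicate 2. The hypoxia call (0.027) was lost without scramble untreated replicate 1 (0.0586), shATF4 untreated replicate 3 (0.0544) or shATF4 48 h replicate 2 (0.0606). DDIT3 differed by -1.22 ± 0.21 (adjusted p = 0.00298). The largest differences were in BOLA2B (5.61, adjusted p = 0.0487), which has near-identical copies and stood at 0.26 (0.956) without shATF4 48 h replicate 1, SEMA3C (1.88, 0.0151), which was lost without scramble 48 h replicate 1 (0.0618) or 2 (0.0934) or shATF4 48 h replicate 1 (0.186), and CHODL (1.87, 0.0189), which was lost without scramble 48 h replicate 1 (0.209) or shATF4 48 h replicate 2 (0.0911) and stood at 2.96 without scramble 48 h replicate 2. CYP11A1 (-3.33, 0.0194) was lost without scramble untreated replicate 1 (0.0533), scramble 48 h replicate 1 (0.0505) or 2 (0.0569) or shATF4 untreated replicate 1 (0.123) or 2 (0.0614). SCEL (-3.23, 0.0304) stood at -1.58 (0.569) without shATF4 untreated replicate 1. AC004233.2 (-3.14, 0.0279) overlaps other genes and was lost without scramble untreated replicate 1 (0.0511) or 3 (0.0655), scramble 48 h replicate 1 (0.0779) or 2 (0.0878), shATF4 untreated replicate 2 (0.113) or shATF4 48 h replicate 1 (0.0751).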

How the results depend on the processing

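Offsets for GC content and length, the fit without both libraries that stood apart and upper-quartile scaling of the lists were chosen after seeing the data. Lists were followed under both scalings, the replicate block, the estimated correlation and with libraries left out, and no called list changed the direction of its test. Named genes were followed under median-of-ratios size factors, DESeq2, the replicate block, fits to the compared groups and single libraries left out. There no called gene changed sign. Single genes were not followed under upper-quartile scaling, without the filter, with offsets or without both libraries. The median of immediate early and AP-1 genes for knockdown untreated did change sign, from -0.117 to 0.006 without scramble untreated replicate 2 and 0.007 without both libraries, where the call was lost (0.101 and 0.108). For the 165 called lists, 1617 results under the alternatives passed and 175 did not. Lists that were not called were followed only as counts of calls, which reached 176 without both libraries. Of the gene results 15551 stayed on the same side of the threshold, 850 lost a call and 253 gained one. With an estimated correlation 59 of the 165 list calls passed. The cause of the shifts in counts below was not tested, except that a 2-fold minimum calls fewer genes by construction.

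Genes called for knockdown in untreated cells numbered 1085 with GC and length offsets and 891 without both libraries. At 24 h knockdown gave 2189 in a fit to the compared groups alone, and at 48 h 2748 in that fit, which turns the order of the times, 2965 with offsets and 3021 without both libraries. The interaction at 24 h gave 798 without a filter, 695 with DESeq2, 173 in the fit to its own groups, 1209 with offsets and 647 without both libraries, and at 48 h 1290 with offsets and 1204 without both libraries. A 2-fold minimum left 90, 419 and 260 genes for knockdown untreated, at 24 h and at 48 h, 1903 and 4189 for 5-FU in scramble cells, 1856 and 3743 in shATF4 cells, 61 and 127 for the interactions, and 1471 and 2297 between 24 h and 48 h in scramble and shATF4 cells.

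With single libraries of the compared groups left out the counts ran from 277 to 456, 2067 to 3885 and 600 to 789 for knockdown untreated, at 24 h and at 48 h, from 6507 to 7297 and 8834 to 10309 for 5-FU in scramble cells, from 6598 to 7538 and 8485 to 9461 in shATF4 cells, from 65 to 1188 and 136 to 487 for the interactions, and from 4363 to 5882 and 6289 to 8165 between the times. Libraries of other groups count too, through the shared estimate of spread, and over all 16 the highest counts were 774, 3885 and 2463 for knockdown, 8261 and 11000 for 5-FU in scramble cells, 7859 and 10628 in shATF4 cells, 1188 and 991 for the interactions, and 7485 and 8587 between the times. No lowest count changed. Called lists ran from 160 to 171 and named genes from 1020 to 1195. Where this left 1 library at 48 h, that sample is assumed to vary like the other groups. At these depths genes with a few counts per group have wide count ratios, and a fold for them is a bound or a range.

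With the replicate number as a block the interaction at 24 h gave 644 genes, and the histone lists at 48 h of 5-FU against untreated lost their calls, with adjusted p-values of 0.0577 in scramble and 0.073 in shATF4 cells. Knockdown gave 591, 3973 and 1967 genes untreated, at 24 h and at 48 h with that block. Whether the numbers pair the libraries stays open. Of 32 same-number pairs 16 had deviations correlated over 0.1, within a range of -0.475 to 0.508. Deviations from the mean of a few libraries sum to 0 within a group, so these correlations do not decide it.

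List medians near 0 that changed sign under a scaling were those of base excision repair, cholesterol synthesis and interferon genes for knockdown untreated, base excision repair at 24 h and DNA replication at 48 h of 5-FU in scramble cells, NRF2 targets at 48 h in shATF4 cells, and fluoropyrimidine genes for knockdown at 24 h and 48 h. In the interactions they were those of amino acid transporters, reticulum chaperones, p53 targets, autophagy and immediate early genes at 24 h and the BCL2 family at 48 h. Between 24 h and 48 h they were colon epithelial genes in scramble cells and homologous recombination and mesenchymal genes in shATF4 cells, and fibroblast markers changed sign for knockdown at 24 h and its interaction.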

Other observations

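Some genes listed as markers of other cell types rose with 5-FU although the libraries are of a cell line. The lysozyme gene LYZ, an immune marker that Paneth cells also express, rose by 2.18 at 24 h and 3.23 at 48 h in scramble cells, and by 1.73 at 24 h in shATF4 cells. The fibroblast marker PDGFRB rose by 2.48 and 2.41 in scramble cells, and THY1 by 4.16 ± 0.66 at 48 h. Of the 4 fibroblast markers measured 3 rose at 24 h in scramble cells (median 1.59, camera adjusted p = 0.00982, but 0.064 with an estimated correlation) and 3 at 48 h (adjusted p = 0.101). Of the 2 endothelial markers measured, VWF rose by 1.30 and PECAM1 by 1.17 at 24 h in scramble cells, and the list did not pass (adjusted p = 0.131). The immune list had 2 of its 8 genes measured and did not pass at 24 h in scramble cells (1 rose, median 0.77, adjusted p = 0.0721) or in shATF4 cells (1 rose, or 1 rose and 1 fell adjusted over the list alone, median 0.13, adjusted p = 0.281). Of the 8 fibroblast and 5 endothelial markers 4 and 2 were measured. The other markers of the 3 lists lay below the filter, such as the leukocyte gene PTPRC, with 4 counts over all libraries, and the collagen gene COL3A1, with 0, both named after their values were seen. Over the same groups the number of genes detected per library rose from a mean of 22120 through 23330 to 25400 in scramble cells and from 22340 through 23640 to 25310 in shATF4 cells.

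Of 14 homologous recombination and Fanconi genes 8 rose and 1 fell at 24 h in scramble cells, or 9 and 1 adjusted over the list alone (median 0.28, camera adjusted p = 0.00158, but 0.222 with an estimated correlation), BRCA1 by 0.70. The cyclin genes CCNE1 and CCNE2, which drive entry into S phase, rose by 1.51 and 1.20, while the DNA replication list, with 13 of 28 genes higher and 6 lower, did not pass (median 0.17, adjusted p = 0.0598). Of 14 autophagy genes 7 rose and 1 fell at 48 h (median 0.30, camera adjusted p = 0.0193, but 0.191 with an estimated correlation), with MAP1LC3B at 1.48. Of 13 BCL2 family genes 8 rose and 1 fell at 48 h (median 0.37, camera adjusted p = 0.022, but 0.0798 with an estimated correlation), the proapoptotic BMF by 2.83 and PMAIP1, also called NOXA, by 1.85. Of 10 drug efflux transporters 7 rose and 2 fell at 48 h in scramble cells and the list did not pass (median 0.96, adjusted p = 0.158), with ABCB1 at 1.33 and ABCC3 at 1.20, and in shATF4 cells ABCB1 rose by 1.91. The folylpolyglutamate hydrolase GGH rose by 1.20 and the folate-retaining enzyme FPGS had -1.11 at 48 h in scramble cells. Of 14 NRF2 targets 4 rose and 3 fell at 24 h in scramble cells, or 6 and 3 adjusted over the list alone, and the list did not pass (adjusted p = 0.717), with a median of -0.08 although the test pointed up.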
